A study of Mus musculus with 16 samples.

How the data were processed

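Per the labels, polyadenylated RNA was isolated with a miRNeasy Mini Kit from perfused, flash-frozen kidneys, and libraries were made with a New England Biolabs Ultra Directional kit. The 16 libraries came from mice congenic for the Kl mutation on 129S1/SvlmJ, 8 males and 8 females of 44 to 54 days. Groups were read from the labels: 3 male controls (+/Kl), 5 male Kl/Kl, 4 female controls (+/+) and 4 female Kl/Kl mice, with 0 libraries left unassigned. Sex went with the table, with the order of the library numbers and, in controls, with heterozygosity.

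The authors deposited TPM values in 2 tables, 1 for each sex, each with 8 libraries and the same 30277 genes (30025 distinct names, 17903 protein-coding, 30 mitochondrial). The submitters' processing notes name genome build mm39 and the program Partek, and the gene annotation is Ensembl's per the file headers. The aligner, the counting method, the use of strand and any filter are not given in the sources used here. Gene starts and stops in the deposited tables are coordinates, used for gene position and span. The values showed how they had been scaled. No value was 0, the lowest genes of each column all stood at about 0.0001 read divided by the genomic span of the gene (introns included, median span 9858 bp), and about 60.3% to 63.6% of low genes then fell on whole reads within a tolerance of 0.05. Each column of a table had the same total, 285327 in males and 265288 in females, a ratio of 1.08 that belongs to the table and not to a library. Because of the division by genomic span, short genes, mitochondrial genes and pseudogenes take large shares of these values, and levels of different genes should not be compared with TPM from transcript lengths. Multiplying each value by its span and dividing by the offset gave estimated depths of 21.5 to 31.7 M reads per library. These are estimates and not counts, so no interval from counting was computed, and precision is given as the spread between libraries.

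Values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with a trend), for genes with a mean of at least 1 TPM over the libraries of the fit. Every log2 change or log2 fold change given is a difference on this scale. Where levels are low it is smaller in size than the log2 ratio of the TPM values. The threshold was a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene is from limma. Kl/Kl was compared with control within males and within females. The difference between the sexes' changes was tested in a 4-group model of all 16 libraries, where a fixed offset per gene between the tables cancels. A direct test of males against females was tried during exploration and set aside, because the tables were scaled separately and sex cannot be told apart from the table. None of its values is given. Kl was also tested with a two-sided exact permutation test in SciPy 1.17.1. Tables were handled with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

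Gene lists were tested with limma's camera, which sets a list against all other genes, with the correlation between genes estimated from the residuals, and as an alternative with a preset correlation of 0.01. Benjamini-Hochberg adjustment ran over the lists of a comparison, for lists with at least 3 measured genes. The 28 lists covered mineral handling, tubular injury, 3 tubule segments, podocytes, endothelium, extracellular matrix, macrophages, lymphocytes, cytokines, interferon, fatty acid oxidation, oxidative phosphorylation, cell cycle, p53, antioxidant genes, unfolded protein response, hypoxia, renin-angiotensin-aldosterone, mineralisation, male-biased and female-biased kidney genes, blood, neutrophils, adjacent tissue, smooth muscle and immediate early genes. The tables list 7 of 8 blood genes, 8 of 10 neutrophil genes and 10 of 15 adjacent tissue genes, and all genes of the other lists. After the data had been seen, 5 lists were added, of heart muscle, airway, alveolar, adipocyte and liver genes.

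Named genes followed a rule. It took Kl, then the 8 largest rises and 8 largest falls among genes with a regular symbol that passed the threshold, had a mean of at least 5 TPM in a group and had groups that did not overlap, which chance alone gives a gene with an exact probability of 0.0357 in males and 0.0286 in females. For the interaction it took the 10 genes with the smallest p and a mean of at least 5 TPM in a group. From each list it took up to 4 members past the threshold, or up to 2 as values, and 5 sex-linked genes checked the sex labels. Of the genes this rule took from the lists, 3 are not reported here. The comparisons, test, filter, pseudocount, lists, naming rule and most alternatives were chosen before the data were examined.

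Alternatives were other pseudocounts and filters, median-of-ratios scaling, array weights, a robust fit, a replicate block, age, the prefix of the library name, a 4-group model and leaving out each library. Added after the data had been seen were fits without male control replicate 3 and female Kl/Kl replicate 3, voom on estimated reads (genes with a mean of at least 10), scaling to the total of nuclear protein-coding genes, and male columns brought to the female total. The division of interaction genes at 1 TPM in female controls was also chosen then. The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold on the log2(TPM + 1) scale. They recovered 62% and 97% of these in the male design, 45% and 74% in the female design, 94% and 100% in females without replicate 3, 25% and 67% in the interaction, and 73% and 86% in the interaction without both libraries, with 3 to 8 false calls each. The simulated noise was independent between genes, with no outlying library and no subgroup of samples. These rates therefore need not hold for the real libraries. All 120 pairs of libraries were checked for duplicates, and the highest Spearman correlation was 0.982. In 4 pairs 255 to 811 values were identical, but at most 2 of them lay above the value of a gene with no read, where columns with nearly equal offsets round to the same number.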

Results

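Polyadenylated RNA was sequenced from kidneys of male and female 129S1/SvlmJ mice, a laboratory inbred strain congenic for a recessive mutation of the Klotho gene (Kl). There were 16 libraries in 4 groups: 3 male controls, 5 male Kl/Kl mice, 4 female controls and 4 female Kl/Kl mice, all between 44 and 54 days old. Per the labels, Kl/Kl mice had renal failure and controls had healthy kidney function. All male controls were heterozygous for the mutation and all female controls were wild type, so the genotype of the controls went with sex. The values were TPM, a read count relative to gene length, deposited in 1 table for each sex, and the estimated depth was 21.5 to 31.7 M reads per library. Because the columns of the male table summed to 285327 and those of the female table to 265288, each sex was tested within its own table. The labels give an age and genotype for every library but do not state that each came from a separate animal, so the p-values measure the spread between these samples.

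Kl, the targeted gene (chromosome 5, 150876072 to 150917283, build mm39), encodes the kidney co-receptor for the phosphate-regulating hormone FGF23. Its level was 15.1, 11.4 and 4.14 TPM in the 3 male controls and 0.0235 to 0.265 TPM in the 5 Kl/Kl males. The group means were 10.2 ± 5.56 TPM (SD, n = 3) and 0.112 ± 0.108 TPM (SD, n = 5), and Kl fell by 3.19 on the log2 scale (SE 0.30, limma adjusted p = 9.58e-05). In females the means were 15.7 ± 5.22 TPM in controls (SD, n = 4) and 0.239 ± 0.224 TPM in Kl/Kl mice (SD, n = 4), a fall by 3.71 on the log2 scale (SE 0.26, limma adjusted p = 0.0035). Kl/Kl means were 1.10% of control in males and 1.53% in females. Every Kl/Kl library lay below every control of its sex, with two-sided exact permutation p = 0.0357 in males and exact permutation p = 0.0286 in females, each the smallest value its design allows. Without male control replicate 3 the Kl/Kl mean was 0.84% of control (exact permutation p = 0.0952), and without female Kl/Kl replicate 3 it was 1.98% (exact permutation p = 0.0571). Both are again the smallest values those designs allow and lie above 0.05. The mean of Kl/Kl males was 0.0735 TPM without replicate 5, and that of Kl/Kl females 0.147 TPM without replicate 4. The X-linked transcript Xist was 12.1 to 43.8 TPM in females and at most 0.404 TPM in males. The Y-linked Ddx3y was 1.34 to 3.86 TPM in males and at most 0.0706 TPM in females, and 0 libraries were out of place for 5 sex-linked genes.

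**Figure D1:**
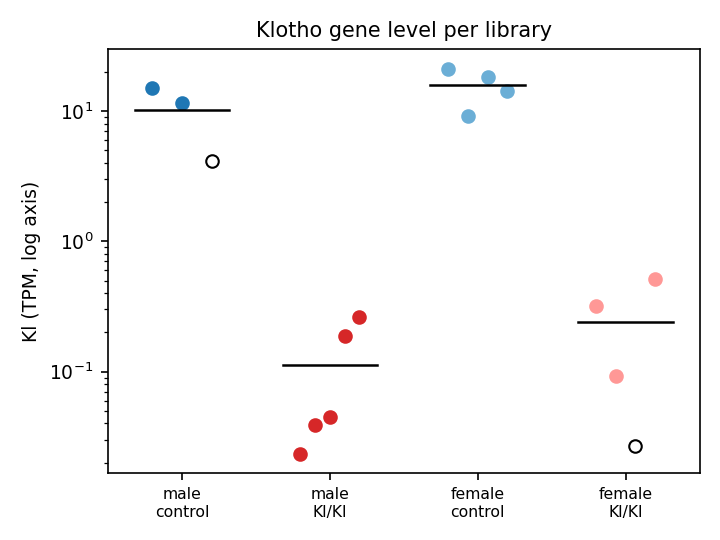
Kl level (TPM, log axis) in each library of the 4 groups, with points for libraries, open points for female Kl/Kl replicate 3 and male control replicate 3, and bars for group means. Controls lie between 4.14 and 21.2 TPM and Kl/Kl libraries between 0.0235 and 0.518 TPM.

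By the median Spearman correlation with all other libraries, female Kl/Kl replicate 3 (0.504) and male control replicate 3 (0.858) stood lowest. Kl/Kl males 4 (0.889) and 1 (0.891) came next, with a correlation of 0.955 with each other, and the other 12 libraries lay between 0.922 and 0.965. In female Kl/Kl replicate 3, genes of the kidney tubule were nearly absent. Umod, the main urinary protein of the thick ascending limb, was 1.68 TPM against at least 67.5 TPM in each of the other 15 libraries. Slc34a1, the proximal tubule phosphate transporter, was 0.343 TPM against at least 89.3 TPM. Heart and airway genes were abundant there, with the atrial peptide gene Nppa at 1185 TPM (at most 0.636 TPM elsewhere). The atrial myosin gene Myl7 was at 453 TPM, and the airway secretoglobin genes Scgb1a1 and Scgb3a1 were at 362 and 420 TPM. Against the median of the other 7 female libraries, the median ratio over the list was 0.00239 for proximal tubule genes, 692 for heart muscle genes, 32384 for airway genes and 171 for adipocyte genes. It was 0.136 for alveolar genes (3 measured) and 0.148 for liver genes. Since its kidney genes were this low, its low Kl level does not check its label. Male control replicate 3 differed less from its group: its median Spearman correlation with the other male controls was 0.896, where the lowest among other pairs of controls of 1 sex was 0.970. Mitochondrial genes took 54.3% of its summed values, against 35.4% to 44.8% in the other 7 male libraries, and its median ratio to the other male controls was 0.443 over proximal tubule genes, while the kidney genes Kap (4081 TPM) and S100g (69.0 TPM), described below, were not lower there. Each comparison is therefore given with and without female Kl/Kl replicate 3 and male control replicate 3, below called the libraries that stood apart. Kl/Kl males 1 and 4 were left out only 1 at a time.

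**Figure D2:**
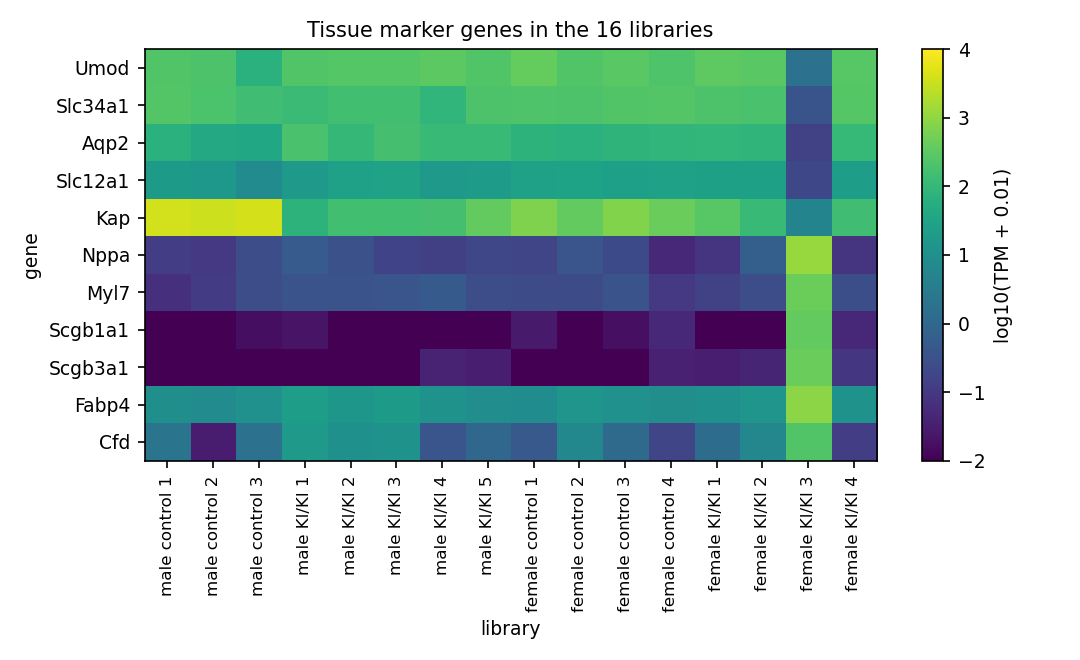
Levels of 11 tissue marker genes, one per line, in the 16 libraries, one per column, coloured by log10(TPM + 0.01). Female Kl/Kl replicate 3 has Umod at 1.68 TPM and Nppa at 1185 TPM, while the other 15 libraries have Umod at 67.5 TPM or more and Nppa at 0.636 TPM or less.

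The male comparison asked which kidney genes differ between mice with renal failure and mice with healthy kidneys. In Kl/Kl males a vitamin D gene, tubular injury genes and the complement gene C3 were higher, while abundant genes with male-biased expression in mouse kidney were far lower. Cyp27b1, which encodes the hydroxylase that makes active vitamin D (chromosome 10, 126884119 to 126888876), rose from 1.32 ± 0.30 TPM (SD, n = 3) to 17.5 ± 4.05 TPM (SD, n = 5), a log2 fold change of 2.98 (SE 0.21, limma adjusted p = 1.54e-05). Kap, the androgen-regulated protein that is among the most abundant transcripts of male mouse kidney (chromosome 6, 133826814 to 133830726), fell from 3813 ± 325 to 184 ± 109 TPM, by 4.54 on the log2 scale (SE 0.38, adjusted p = 5.29e-05). The injury gene Lcn2, which encodes a lipocalin released by damaged tubules, rose from 0.582 ± 0.162 to 4.93 ± 1.95 TPM (log2 1.84, adjusted p = 0.00191).

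The 8 largest rises among named genes past the threshold ran from log2 3.33 to 6.11 in males. Cyp4a14, a fatty acid omega-hydroxylase, went from 0.198 ± 0.147 TPM in controls to 111 ± 115 TPM in Kl/Kl males, where the mean was 59.7 TPM without replicate 4; that of controls was 0.118 TPM without replicate 2. Apoe, a lipoprotein carrier of cholesterol (chromosome 7, 19430034 to 19433114), went from 63.0 ± 22.3 to 862 ± 193 TPM. Hpd, an enzyme of tyrosine breakdown, went from 7.24 ± 0.0772 to 115 ± 37.3 TPM. C3, the central complement component (chromosome 17, 57510970 to 57535137), went from 0.636 ± 0.367 to 24.6 ± 22.7 TPM (14.7 TPM without Kl/Kl replicate 1). The other 4 were Gc, the vitamin D carrier of plasma, Serpina6, the corticosteroid carrier, and the glucuronosyltransferase genes Ugt1a1 and Ugt1a2, which share exons, so that reads can be shared between them. Their values did not move together in every library. Ugt1a1 and Ugt1a2 were 17.1 and 52.6 TPM in Kl/Kl male replicate 1 and 29.1 and 15.4 TPM in replicate 4. In each of these 8 genes every female control also lay above every male control. The tables were scaled separately, and no test was made. Female controls had 39.7 to 70.2 TPM of Cyp4a14, 308 to 391 of Apoe, 32.2 to 63.1 of Hpd and 2.84 to 6.46 of C3. Every Kl/Kl male lay above these ranges for Apoe, Hpd and C3, while for Cyp4a14 they overlapped. The 8 largest falls ran from log2 -3.62 to -4.80 and were Cyp2a4, Kap, Acsm3, Acy3, Ces1f, Slc22a7, Akr1c14 and Cyp4b1. Rises and falls were ranked on the log2(TPM + 1) scale, which is not a ranking by the ratio of TPM. Ugt2b37, given below, fell to a smaller share of its control level than Cyp4b1 but ranked after it. Acsm3, a medium-chain acyl-CoA synthetase (chromosome 7, 119360146 to 119386737), went from 29.3 ± 11.3 to 0.275 ± 0.216 TPM (0.183 TPM without Kl/Kl replicate 5). The aminoacylase gene Acy3 went from 649 ± 156 to 43.6 ± 35.5 TPM and the organic anion transporter gene Slc22a7 from 16.9 ± 6.25 to 0.234 ± 0.149 TPM. In each of these 16 genes every Kl/Kl male lay beyond every control, which the naming rule required, and adjusted p lay between 3.18e-06 and 0.0044. Cyp4a14, Cyp2a4 and Ces1f belong to families of near-identical copies whose reads can be shared.

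**Figure D3:**
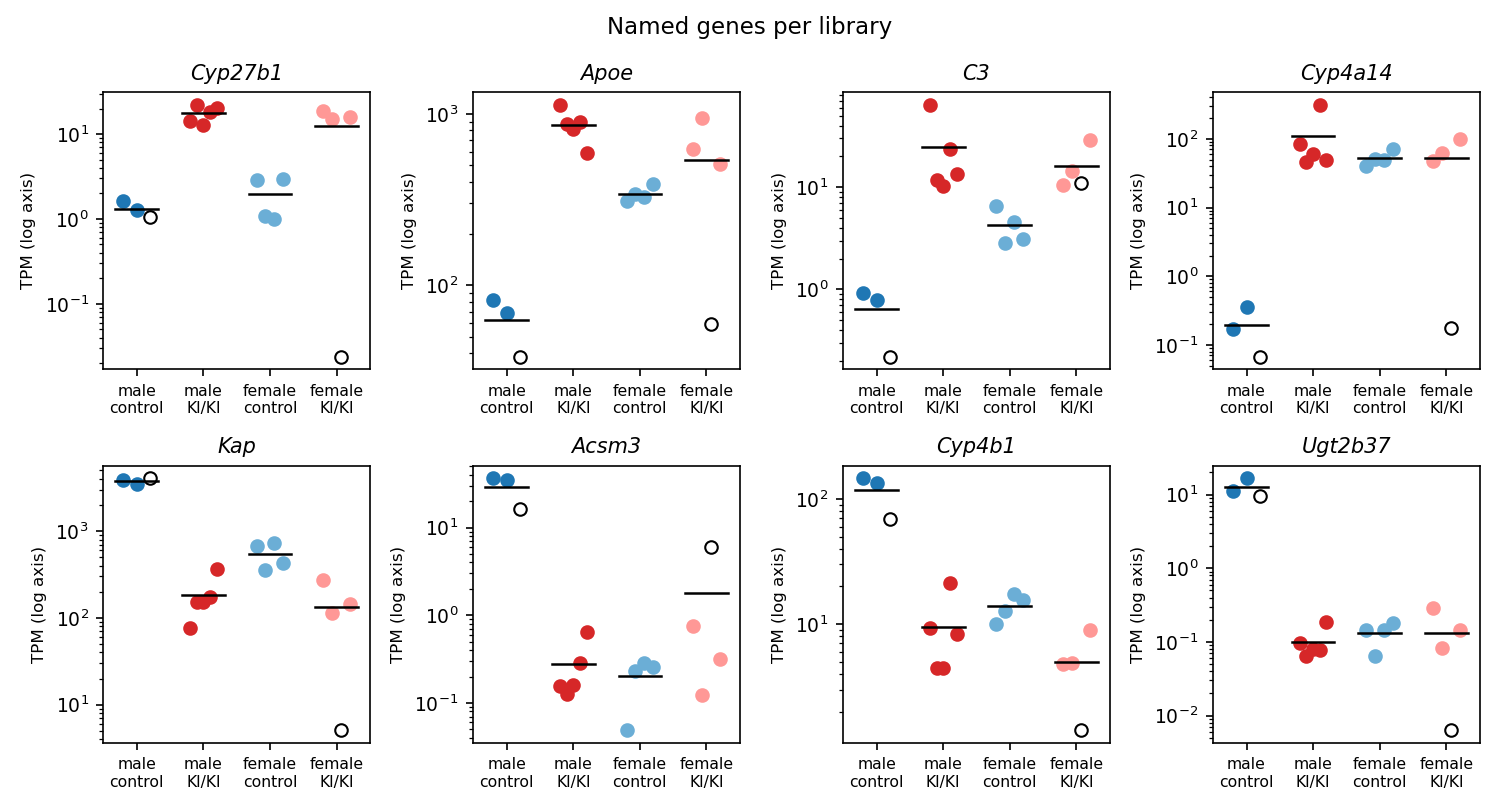
Levels (TPM, log axis) of 8 named genes in each library of the 4 groups, with points for libraries, open points for the libraries that stood apart, and bars for group means. Cyp27b1 averages 1.32 TPM in male controls and 17.5 TPM in Kl/Kl males, and Kap 3813 and 184 TPM; male and female tables were scaled separately.

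Of the gene lists, the male-biased kidney genes moved most in males. Of 15 measured members 12 fell, 13 adjusted over the list alone, and the median log2 fold change was -3.14. Besides Kap, Acsm3 and Cyp4b1, the steroid and drug glucuronosyltransferase gene Ugt2b37 fell from 12.5 ± 3.70 to 0.101 ± 0.0502 TPM (log2 -3.59, adjusted p = 7.37e-07). Set against all other genes with an estimated correlation between genes, camera gave this list an adjusted p = 0.0337, the only 1 of 25 lists past the threshold. That call held without male control replicate 1 (adjusted p = 0.0337). It was lost, by adjusted p, without male control replicate 2 (0.0508) or 3 (0.0949) and without Kl/Kl replicate 1 (0.0621), 2 (0.0711), 3 (0.0760), 4 (0.0725) or 5 (0.0573). It was also lost with replicate numbers as a block (adjusted p = 0.556) and with voom on estimated reads (adjusted p = 0.124). Without male control replicate 3, 12 of 15 members fell, 14 adjusted over the list alone. Of the 6 female-biased genes, Cyp4a14 rose and Slc22a7 and Rnf24 fell, and adjusted over the list alone 2 rose and 4 fell. Slc22a7 was 5.28 to 16.4 TPM in female and 10.8 to 23.3 TPM in male controls, and Rnf24 1.27 to 3.00 and 3.17 to 3.54 TPM. These fallers were thus not higher in female controls here, while Cyp4a14 was (39.7 to 70.2 against at most 0.357 TPM). No test was made across the separately scaled tables. The female-biased list is named for its planned members. Its median was -1.39, which turned to 2.09 over 10 genes with voom on estimated reads, and its preset-correlation adjusted p = 0.00632 became adjusted p = 0.212 with an estimated correlation.

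Genes of mineral handling and the nephron moved in part. In the phosphate, calcium and vitamin D list, 2 of 16 members rose over all genes and 2 adjusted over the list alone. They were Cyp27b1 and S100g, a calcium-binding protein of the distal tubule, which went from 56.1 ± 12.2 to 184 ± 21.7 TPM (log2 1.71, adjusted p = 0.000791). In the tubular injury list 4 of 12 rose, 6 adjusted over the list alone. They included Spp1 (osteopontin, 62.2 ± 22.5 to 230 ± 38.3 TPM, log2 1.92, adjusted p = 0.00171), Lcn2 and Krt18 (log2 1.19). Camera with a preset correlation placed this list above other genes (adjusted p = 0.00934), and with an estimated correlation the adjusted p = 0.779. Of 30 proximal tubule genes 1 rose and 3 fell (2 and 3 adjusted over the list alone). The lactate transporter Slc5a12 rose (log2 2.01). The organic anion transporter Slc22a6, the glutathione enzyme Ggt1 and the urate transporter Slc22a12 fell (log2 -1.70, -1.20 and -1.11). The list's median was -0.02, its mean 0.01, and its test pointed down. In the thick ascending limb and distal convoluted tubule list 1 of 17 rose, and 1 adjusted over the list alone. In the collecting duct list the water channel Aqp2 and the sodium channel subunit Scnn1g rose (2 of 17, 6 adjusted over the list alone; log2 1.45 and 0.51). In the podocyte list 1 of 8 rose, 3 adjusted over the list alone. The call of Aqp2 ended without male control replicate 2 (adjusted p = 0.0633), and those of Slc22a6 and Ggt1 without male control replicate 1 or 2 (up to 0.0832 and 0.0807). Those of Krt18, Slc5a12, Slc22a12 and Scnn1g ended without male control replicate 2 and also without 3 or more of the other libraries, with adjusted p up to 0.0821, 0.0638, 0.122 and 0.0932.

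Immune and matrix genes were mixed. In the macrophage list 3 of 8 rose, and adjusted over the list alone 4 rose and 1, the receptor gene Csf1r, fell. The 3 were the lipopolysaccharide receptor Cd14 (2.13 to 8.10 TPM, adjusted p = 0.00568), the lysozyme gene Lyz2 (1.91 to 6.65 TPM, log2 1.39, adjusted p = 0.00326) and Cd68 (log2 0.75). Both measured genes of the lymphocyte list fell, as they did adjusted over the list alone (2 of 2). The antibody light chain gene Igkc went from 84.8 ± 0.737 to 13.5 ± 11.2 TPM, and it fell with the antibody joining chain gene Jchain (log2 -2.98 and -1.37). Female controls had 5.28 to 33.0 TPM of Igkc and 0.164 to 0.845 TPM of Jchain, near Kl/Kl males (3.61 to 26.6 and 0.0839 to 0.700 TPM). Male controls thus stood above healthy females too, although the tables were scaled separately and no test was made. In the extracellular matrix list Lox, which cross-links collagen, and Thbs1 rose (2 of 12, 6 adjusted over the list alone; log2 1.28 and 0.84). Its preset-correlation adjusted p = 0.00934, and with an estimated correlation adjusted p = 0.779. Of 6 cytokine genes C3 rose (3 adjusted over the list alone), and of 6 interferon genes Ifit2 rose (log2 0.84; 2 adjusted over the list alone). Of 8 immediate early genes the transcription factor Klf6 rose (log2 1.06; 4 adjusted over the list alone). Among 8 endothelium, 4 smooth muscle, 5 blood and 4 adjacent tissue genes limma called 0 over all genes and 0 adjusted over the list alone, with 3, 1, 0 and 0 at an unadjusted p under 0.05, and voom on estimated reads called 1, 0, 0 and 0. No neutrophil gene had a mean of 1 TPM, and voom called 1 of 4. Plvap of the endothelium was 8.83 against 15.0 TPM, Tagln of smooth muscle 3.67 against 6.91 TPM, Hba-a2 of blood 39.1 (22.6 without control 2) against 72.3 TPM and Cfd of fat 1.29 against 7.89 TPM. The call of Igkc ended without male control replicate 2 (adjusted p = 0.0512). Those of Lox, Thbs1, Cd68 and Klf6 ended without it and also without 3 or more of the other libraries, with adjusted p up to 0.0796, 0.0839, 0.103 and 0.0822.

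Metabolic and stress lists changed in single members. Among 23 genes of fatty acid oxidation and peroxisomes 3 rose and 1 fell, and adjusted over the list alone 9 rose and 1 fell. Cyp4a14, its paralog Cyp4a10 (log2 3.00) and the thiolase Acaa2 (0.95) rose, and the acyl-CoA dehydrogenase Acadm fell (-0.98). The preset-correlation adjusted p = 0.0339, and adjusted p = 0.779 with an estimated correlation. Of 28 oxidative phosphorylation genes the cytochrome c gene Cycs fell (26.1 ± 2.52 to 10.6 ± 2.55 TPM, log2 -1.25, adjusted p = 0.0081; 1 adjusted over the list alone). The list's median was 0.09, its mean 0.02, and its test pointed down. Of 17 antioxidant genes the glutathione transferase Gsta4 (0.452 to 3.85 TPM, log2 1.66) and the epoxide hydrolase Ephx1 (0.59) rose and the glutamate-cysteine ligase subunit Gclm fell (-0.98). Adjusted over the list alone 4 rose and 2 fell, with a median of 0.07, a mean of 0.14 and a test that pointed down. In the hypoxia list the kinase Pdk1 and the glucose transporter Slc2a1 rose (2 of 11, 4 adjusted over the list alone; log2 0.98 and 0.65). In the renin-angiotensin-aldosterone list the angiotensin precursor gene Agt and the kinase Sgk1 rose (2 of 9, log2 0.96 and 0.85), and adjusted over the list alone 3 rose and 1, Ace, fell. In the mineralisation list Spp1 rose (1 of 5, and 1 adjusted over the list alone). Among 2 cell cycle, 11 p53 and 12 unfolded protein genes limma called 0, with 1, 5 and 2 at an unadjusted p under 0.05 and 1, 0 and 0 adjusted over the list alone, and voom on estimated reads called 1, 1 and 5. The replication clamp gene Pcna was 5.32 against 8.27 TPM, Ccng1 of the p53 list 22.4 against 24.8 TPM and the chaperone gene Calr 125 against 66.4 TPM. The call of Cyp4a10 ended without male control replicate 3 (adjusted p = 0.0512). Those of Acadm, Acaa2, Gclm, Ephx1, Pdk1, Slc2a1, Agt and Sgk1 ended without male control replicate 2 and also without 4 or more of the other libraries, with adjusted p up to 0.127, 0.0953, 0.114, 0.0893, 0.0884, 0.106, 0.0748 and 0.115.

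In total 500 of 8439 genes passed limma's threshold in males, 316 higher and 184 lower in Kl/Kl mice. On the log2(TPM + 1) scale 264 of them changed at least 2-fold. The median gene lay at log2 0.19 on the deposited scale, and relative to it the medians were -3.33 for male-biased, 0.26 for tubular injury and -0.21 for proximal tubule genes. After median-of-ratios scaling, which put the median gene at 0.01, the split was 487 higher and 695 lower, and the medians of the phosphate, antioxidant and oxidative phosphorylation lists changed sign. Without male control replicate 3 there were 909 calls, 273 higher and 636 lower. Of these, 382 were among the 496 calls also tested there, all in the same direction. The count was 282 and 185 without male control 1 or 2, and 237, 276, 314 and 265 without Kl/Kl replicate 1, 2, 3 or 4.

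The female comparison asked the same question in females. Without female Kl/Kl replicate 3, Cyp27b1 rose from 1.96 ± 1.08 TPM (SD, n = 4) to 16.5 ± 1.84 TPM (SD, n = 3), a log2 fold change of 2.63 (SE 0.26, limma adjusted p = 0.0162), and Kl fell (log2 -3.63, adjusted p = 0.00157). With all 4 Kl/Kl libraries Cyp27b1 averaged 12.4 ± 8.37 TPM and did not pass (log2 1.61, adjusted p = 0.745). Of 456 male calls tested in females without replicate 3, 6 passed there, all in the same direction: Kl, Cyp27b1 and 4 that are given below (Gm45315, Gm5454, 5930430L01Rik and Chrna4). These genes of the male comparison did not pass: C3 was 4.24 ± 1.66 TPM in controls and 17.9 ± 9.63 TPM in Kl/Kl mice (adjusted p = 0.0852), Apoe 341 ± 35.4 and 694 ± 225 TPM (adjusted p = 0.0878), S100g 75.5 and 147 TPM (adjusted p = 0.052), Lcn2 0.977 (0.611 without control 1) and 3.28 TPM (adjusted p = 0.094), and Kap 550 ± 187 and 177 ± 83.1 TPM (log2 -1.66, adjusted p = 0.0911). With all 4 Kl/Kl libraries their log2 changes were 1.65, 0.11, -0.69, 1.38 and -2.86 in that order (adjusted p from 0.729 to 0.946), so that of S100g turned from 0.95 to negative.

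With all 8 female libraries, 3 of 8596 genes passed, all lower in Kl/Kl mice: Kl and the processed pseudogenes Gm45315 and Gm5454, whose reads can come from their parent genes. Without replicate 3, 9 of 8748 genes passed, 5 higher and 4 lower, and the 3 genes were among them. The added 6 were Cyp27b1, the pseudogenes Gm6520, Gm16199 and Rpl13a-ps1, the noncoding 5930430L01Rik, and, lower, the nicotinic receptor gene Chrna4; genes other than Kl and Cyp27b1 are named here after their values were seen. The median gene lay at log2 -0.16 with replicate 3 and 0.06 without it, the number at an unadjusted p under 0.05 went from 414 to 1614, and the count was 5 without Kl/Kl replicate 4. After median-of-ratios scaling without replicate 3 the count was 4, with 1 higher and 3 lower.

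Without replicate 3, 0 of 25 lists passed camera with an estimated correlation in females (5 at an unadjusted p under 0.05; 0 of 27 with voom on estimated reads), and 4 lay higher and 5 lower with the preset correlation. The proximal tubule list had a median of -0.13 (adjusted p = 0.188 with an estimated correlation). The thick ascending limb list stood at -0.12 (0.188), the unfolded protein list at -0.27 (0.362) and the female-biased list at -0.73 (0.188). The extracellular matrix list stood at 0.27 (0.606), and the tubular injury, cytokine and immediate early lists at 0.31 (0.606), 0.39 (0.606) and 0.29 (0.188). Over all genes Cyp27b1 was the only list member to pass. Adjusted over the list alone, 5 of 13 tubular injury genes rose and 1 fell, and 5 of 9 interferon genes rose and 1 fell. On the same basis 3 of 13 unfolded protein genes fell, namely Sdf2l1, Hsp90b1 and Calr, and of 8 female-biased genes 5 fell, among them Rnf24 and Slc22a7. Of 8 male-biased genes 2 rose and 4 fell adjusted over the list alone, with a median of -0.42 (0.21 over 18 genes with voom on estimated reads) and adjusted p = 0.188 with an estimated correlation. Medians and means were positive where the test pointed down for the phosphate, collecting duct, endothelium, fatty acid oxidation and antioxidant lists, and the renin-angiotensin-aldosterone list had a median of 0.09, a mean of -0.01 and a test that pointed down. With replicate 3, 0 of 26 lists passed with an estimated correlation (2 at an unadjusted p under 0.05, smallest adjusted p = 0.197). With the preset one 9 lay higher and 5 lower, among them extracellular matrix (median 1.02, adjusted p = 0.301 with an estimated correlation) and proximal tubule (-1.18, 0.703), beside the high heart and airway genes and low tubule genes of that library. Medians and means were negative where the test pointed up there for the fatty acid oxidation, oxidative phosphorylation and hypoxia lists, and the mineralisation list had a median of -0.03, a mean of 0.31 and a test that pointed up.

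The interaction asked whether the change in Kl/Kl mice differed between the sexes, and a fixed per-gene offset between the tables cancels in it. Several of the genes with the smallest p fell in Kl/Kl males and were near 0 in female controls. The fatty acid hydroxylase gene Cyp4a12a was 9.56 ± 1.29 TPM in male controls (SD, n = 3) and 0.174 ± 0.0893 TPM in Kl/Kl males, while female controls and Kl/Kl females without replicate 3 were at 0.104 and 0.179 TPM. The difference between the sexes' log2 changes was -3.20 (SE 0.15, limma adjusted p = 1.37e-08). Ugt2b37 (-3.58, adjusted p = 4.59e-08), the organic anion transporter Slco1a1 (-3.67, adjusted p = 7.78e-06), Cyp2j13 (-3.26, adjusted p = 2.74e-05) and Acsm3 (-5.29, adjusted p = 0.000538) also had a more negative change in males, each with a group mean of at most 0.401 TPM in female controls and in Kl/Kl females without replicate 3. No female control exceeded 0.284 TPM in any of these 5 genes. On the log2(TPM + 1) scale they thus had almost no room to fall in females, and the interaction largely restates their fall in males. These differences and adjusted p come from all 16 libraries, with female Kl/Kl replicate 3 included. Acsm3 was 6.03 TPM in that replicate, so its -5.29 goes beyond its fall in males. The rest of the 10 genes with the smallest p were Eif1ad4 (-3.51), Ces1f (-3.55), the steroid dehydrogenase Akr1c14 (-2.41), the ribonucleoprotein gene Nhp2 (-1.55) and a copy of the noncoding RNA 7SK (-2.19). Akr1c14 did not pass without male control replicate 1 (adjusted p = 0.0558), and several of these have near-identical copies. In each of the 10 genes every male control lay above every other library of either sex. Nhp2 was 12.9 to 17.3 TPM in male controls and at most 6.55 TPM elsewhere, Eif1ad4 3.99 to 16.2 and at most 0.255 TPM, and 7SK 3.62 to 8.21 and at most 1.13 TPM. A trait of the heterozygous male controls cannot be told apart from a response that differs by sex.

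In the interaction 18 of 8535 genes passed, all 18 lower, that is, with a more negative change in males, and in 13 of them the mean of female controls was under 1 TPM. Of 14 male-biased genes 7 passed, 9 adjusted over the list alone, and the median was -1.99. Camera with an estimated correlation gave adjusted p = 0.000171, the only call among 26 lists. The 7 that passed all had a female control mean under 1 TPM. Of the 7 members at 1 TPM or more in female controls, which had room to fall, limma called 0 (2 at an unadjusted p under 0.05; median -1.19). The camera call held with each of the 16 libraries left out (adjusted p up to 0.000915). With the preset correlation 9 lists passed, and of the other 8 the T and B lymphocyte list came nearest (adjusted p = 0.245 with an estimated correlation). Medians and means were positive where the test pointed down for the tubular injury, oxidative phosphorylation, antioxidant, unfolded protein and mineralisation lists, and the adjacent tissue list had a median of -0.34, a mean of 0.06 and a test that pointed down. Without both libraries that stood apart 338 of 8696 genes passed, 40 higher and 298 lower, and the 17 of the first calls that were tested there all passed again in the same direction. Of these 298, female controls averaged under 1 TPM in 25 and at least 1 TPM in 273 (median -0.81). In that fit 11 of 14 male-biased genes were lower (12 adjusted over the list alone; median -2.86, adjusted p = 0.00196), among them Kap (log2 -2.83, adjusted p = 0.0301), and Cyp4a14 and the prolactin receptor gene Prlr of the female-biased list were higher (log2 5.68 and 1.18). Of the 7 male-biased members at 1 TPM or more in female controls 4 passed there (5 at an unadjusted p under 0.05; median -2.27). The median gene of the interaction lay at 0.33 with all libraries and -0.06 without those libraries, and after median-of-ratios scaling of all libraries 30 genes passed, 6 higher and 24 lower. The count was 9 and 10 without male control replicate 1 or 2 and 75 without female Kl/Kl replicate 3.

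Across the 8144 genes tested in both sexes the log2 changes had Pearson r = 0.323 and Spearman rho = 0.229; genes are not independent replicates, the fits share no library, and no p-value was computed. Of the 457 male calls tested in females 301 had the same sign there. Without both libraries that stood apart r was 0.589 and rho 0.554, and 707 of 858 male calls had the same sign; r was 0.549 without female Kl/Kl replicate 3 alone.

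**Figure D4:**
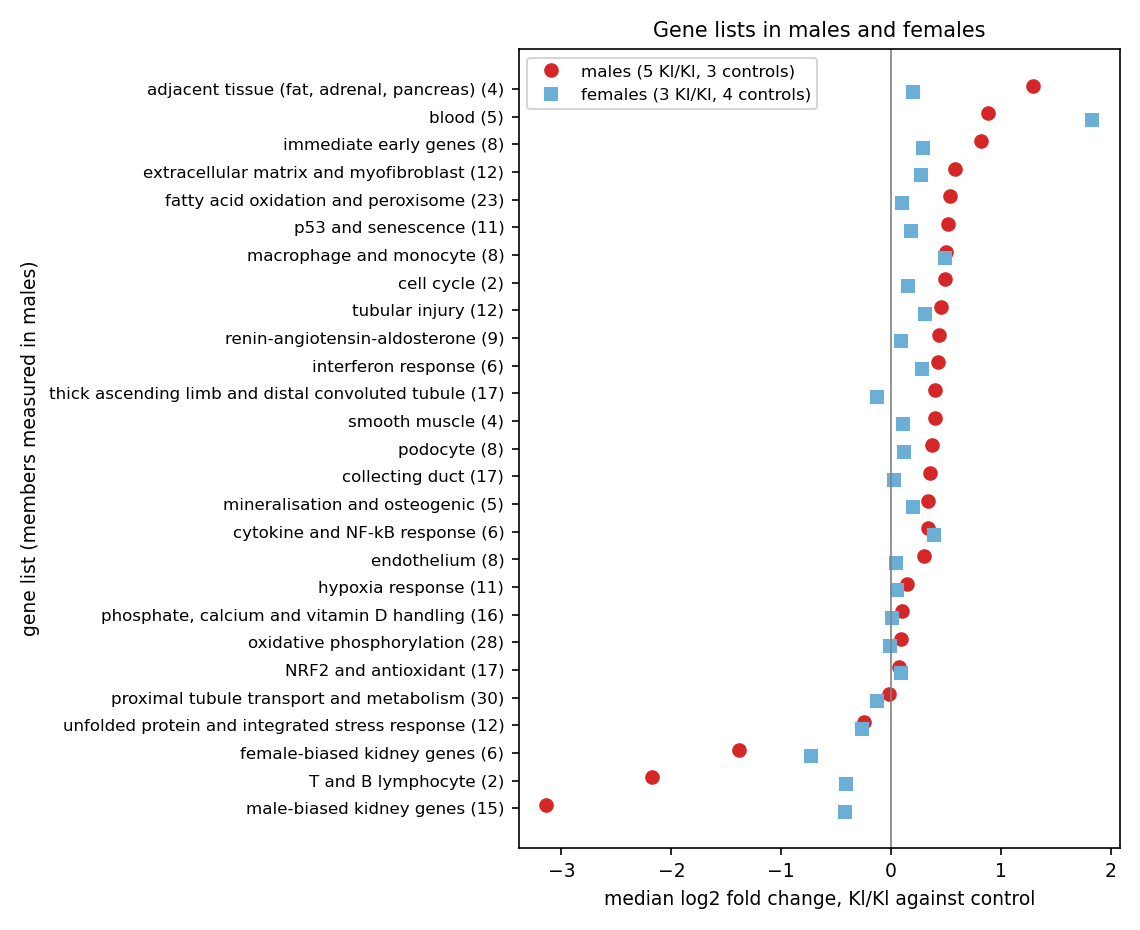
Median log2 fold change (Kl/Kl against control, horizontal axis) of each gene list in males (circles, 8 libraries) and in females without replicate 3 (squares, 7 libraries), with the number of members measured in males in brackets. The male-biased list lies at -3.14 in males and -0.42 in females (0.21 with voom on estimated reads).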

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

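Tests of another tissue, of disease, of scaling, of the column totals, of proximal tubule cells and of heterozygous controls were chosen after the result was seen, while those of transcript length, GC content and other splits were planned.

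Female Kl/Kl replicate 3 lay far from the other libraries of its group. Its median Spearman correlation with its own group was 0.518 (gap over range 1.00) and its median-of-ratios factor 0.432 (gap 0.95). The test of another tissue in place of kidney gave 0.00601 as the highest of its 3 tubule list ratios, with heart and airway ratios of 692 or more, which is in line with RNA that came mainly from tissue other than kidney. Kidney disease alone is argued against, since 22 of 23 heart and airway genes exceeded 10 times the highest of the other 15 libraries (Nppa 1185 TPM, Myl7 453 TPM). Ratios were 29.3 for smooth muscle, 8.89 for matrix, 10.5 for macrophage, 18.1 for lymphocyte, 11.2 for blood, 5.85 for neutrophil and 16.8 for adjacent tissue genes, while how that RNA entered the library, by dissection or by a wrong sample, stays open.

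Male control replicate 3 lay apart from the other male controls. Scaling to a fixed column total is argued against as its cause, because its median rank correlation with controls 1 and 2 was 0.896, below the lowest of other control pairs (0.970). GC content is argued against too, with a correlation across genes of 0.122 where other controls reached 0.303. Transcript length remains open: its correlation of -0.168 was larger in size than that of any other control (0.117) but under the 0.3 set for a length effect. No biological explanation was tested for this library.

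Male-biased kidney genes fell in Kl/Kl males. The column totals and male control replicate 3 are argued against as the cause, since the list's median stayed at -3.11 without that library and with median-of-ratios scaling. An even loss of proximal tubule cells is argued against as the whole cause. The proximal tubule list had a median of -0.0201 (quartiles -0.43 and 0.52), against -3.14 for the male-biased list (upper quartile -1.62). That list does not separate parts of the proximal tubule, so a loss of cells in a part of it was not tested. The heterozygous genotype of the controls cannot be told apart from the male control group, because 0 male controls lacked the mutant allele. Renal failure with lower androgen action in Kl/Kl males may be a biological explanation, and hormone levels were not analysed here.

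Of 60 measures tested in each group of 4 or 5 libraries, about 1 in 20, or 3, would lie far out by chance. In Kl/Kl males 6 did, with a gap over range of 0.71 for Gc and 0.72 for S100g (replicate 5 lowest), 0.73 for Ugt2b37 (replicate 5 highest), 1.00 for Eif1ad4 (replicate 3 highest), and 0.74 for Cyp4a10 and 0.76 for Pdk1 (replicate 4 highest). In female controls 4 did, all as the highest library: Eif1ad4 at 0.97 (replicate 3), 7SK at 0.84 (replicate 4), and Slc22a12 at 0.93 and Scnn1g at 0.90 (replicate 1). In Kl/Kl females 21 did, 19 of them from replicate 3. Its gene levels were lowest for Cyp4a14 (0.83), Ugt1a2 (0.88), Cyp27b1 (0.93), S100g (0.93), Slc5a12 (0.91), Slc22a6 (0.98), Ggt1 (0.97), Slc22a12 (0.93), Aqp2 (0.95), Scnn1g (0.92), Cyp4a10 (0.86), Gclm (0.88) and Slc2a1 (0.84). They were highest for Igkc (0.92), Jchain (0.98), Acaa2 (0.86) and Klf6 (0.91), and Slco1a1 (0.89, replicate 1) and 7SK (1.00, replicate 4) were highest in other libraries.

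The interaction test found a more negative log2 change in males for Cyp4a12a (-3.20), Ugt2b37 (-3.58), Slco1a1 (-3.67), Cyp2j13 (-3.26), Eif1ad4 (-3.51), Acsm3 (-5.29), Nhp2 (-1.55), Ces1f (-3.55), 7SK (-2.19) and Akr1c14 (-2.41), with adjusted p from 1.37e-08 to 0.0069. In each of them every male control lay above every other library of either sex, and a trait of the heterozygous male controls cannot be told apart from sex. For Acsm3, a level of 6.03 TPM in female Kl/Kl replicate 3 added to the -5.29. In 13 of the 18 genes that passed, female controls averaged under 1 TPM, so the test largely restates the fall in males for these. Without both libraries that stood apart this held for 25 of the 298 genes with a more negative change in males, while 273 averaged at least 1 TPM. Other splits of the libraries reached more calls than that fit, as given next.

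Other splits of the same libraries were counted for each number of calls. In males 1 of 56 splits, the real one, gave as many as the real 500 genes (highest other 1). That is the smallest share that 56 splits allow, and it argues against chance without excluding it. In the interaction 1 of 100, the real one, gave as many as the real 18 genes (highest other 0). With and without both libraries, the other interaction splits were drawn at random within each sex. They used values with the sex and genotype effects removed and negative values set to 0, while the real counts used unaltered values. Chance is argued against for the 18 genes only as far as those values stand for the deposited ones. In females 1 of 35 splits gave as many as the real 3 genes (highest other 0), and without replicate 3 1 of 35 gave as many as the real 9 (highest other 1), the smallest share that 35 splits allow. By that share chance is argued against for these counts too, but it is not excluded. Each count includes Kl, whose mutation defines the groups, and 3 genes are few. In the interaction without both libraries, 3 of 100 splits gave at least the real 338 genes. The other 2 had 805, the highest, and 795. Both put male controls 1 and 2 with Kl/Kl males 2, 3 and 5, against Kl/Kl males 1 and 4. The split with 805 also put female controls 1 and 2 with Kl/Kl female 2, and the split with 795 female controls 1 and 4 with Kl/Kl female 4. Counts above the real one point to a structure of the samples beside the groups, and its source was not tested. The other 2 of the 4 drawn splits with these males gave 1 gene each.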

How the results depend on the processing

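The fits without male control replicate 3 and female Kl/Kl replicate 3, voom on estimated reads, the nuclear protein-coding total and the column total matched between the sexes were chosen after the data were seen. Under the alternatives run, no gene taken as past the threshold in males or the interaction, no called list, and neither Kl nor Cyp27b1 in females changed direction. Genes that did not pass in females were run only with and without replicate 3, and S100g turned from log2 -0.69 to 0.95. Why a count changed was not tested. In males the main count of 500 became 322 with a mean TPM of at least 5, 1182 with median-of-ratios scaling, 2829 with array weights, 227 with the replicate block, 1658 with the library name prefix as a block and 1339 with the nuclear protein-coding total (895 higher, 444 lower). It was 909 without the doubtful library, 1149 with median-of-ratios scaling in addition, 2717 with voom (1097 higher, 1620 lower) and 2226 with voom without that library. It ranged from 185 (without male control replicate 2) to 909 (without male control replicate 3) with 1 library left out. It stayed within 1.5 times with a pseudocount of 0.1 (501) or 5 (452), no filter (542), a robust fit (585), age (498) and the 4-group model (380). In females the main count of 3 became 8 with no filter, 327 with array weights (239 higher, 88 lower), 7 in the 4-group model and 9 without replicate 3. It was 0 with the replicate block (limma, 261 at an unadjusted p under 0.05), 0 with voom (624 at an unadjusted p under 0.05) and 26 with voom without replicate 3, and it ranged from 2 (without female control replicate 1) to 9 (without female Kl/Kl replicate 3) with 1 library left out, with 5 without Kl/Kl replicate 4. In the interaction the main count of 18 became 10 with a pseudocount of 0.1, 117 with no filter, 3 with a mean TPM of at least 5, 30 with median-of-ratios scaling, 1036 with array weights, 9 with the replicate block and 31 with age. It was 338 without both libraries, 290 with median-of-ratios scaling in addition, 65 with voom and 609 with voom without both, and ranged from 9 (without male control replicate 1) to 75 (without female Kl/Kl replicate 3), with 10 without male control replicate 2. It was 21 with a pseudocount of 5, 18 with a robust fit, 14 with the prefix block, 24 with the nuclear total and 17 with male columns at the female total. Whether replicate numbers pair the libraries stays open. Libraries of the same sex and number had adjacent library numbers, where both groups held that number. Female pairs 1, 2 and 4 and male pair 1 also had the same age and the same name prefix. Female pair 3 shared the prefix but not the age (49 and 54 days). Male pair 2 shared the age only and male pair 3 the prefix only. Of these pairs, 0 of 3 in males and 1 of 4 in females correlated above 0.1. In females 2 of 4 matched best with their own number, and pair 4 reached 0.291 against at most 0.00890 with other numbers. The group means used for this included the libraries that stood apart, so pairing cannot be excluded.

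Kl was run with a pseudocount of 0.1, median-of-ratios scaling, the replicate block, each library left out, and without the libraries that stood apart. It fell in each of these, and in females with the replicate block its log2 change of -3.71 did not pass (adjusted p = 0.126). The correlation of the male and female changes (0.323) was 0.589 without both libraries and 0.590 with median-of-ratios scaling in addition, and ranged from 0.244 (without female Kl/Kl replicate 2) to 0.549 (without female Kl/Kl replicate 3). With the preset correlation of 0.01, 5 lists passed in males, 14 in females and 9 in the interaction. The single male list call went to 0 with the replicate block, without male control replicate 3 and with voom (adjusted p of the male-biased list 0.556, 0.0949 and 0.124, with 1 list at an unadjusted camera p under 0.05 in each of the last pair), and ranged from 0 to 1 with 1 library left out. Of 52 genes that the naming rule took and that passed in males, 20 did not with the replicate block, 24 in at least 1 fit with a library left out, 9 without male control replicate 3 (among them Acaa2, Cd68, Cyp4a10, Klf6, Lox, Pdk1, Sgk1 and Slc2a1), 5 with a pseudocount of 5, 2 with median-of-ratios scaling (Cd68 and Sgk1) and 1 with a pseudocount of 0.1 (Scnn1g). Of 10 interaction genes, 7SK, Akr1c14 and Nhp2 did not pass with the replicate block, 7SK, Akr1c14 and Ces1f with a pseudocount of 0.1, and Nhp2 with median-of-ratios scaling. Males against females, in controls and in Kl/Kl mice, was fitted during exploration and then set aside, since the tables were scaled separately. Its alternatives were not run in the final analysis.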

Other observations

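The test of genes near Kl was planned, and the interval used to read it was added after its value was seen, as were the lists of other tissues.

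Genes of the unfolded protein response, which code for chaperones of the endoplasmic reticulum, did not pass in the comparison of all male libraries. Without male control replicate 3, Calr, Hspa5, Hsp90b1 and Pdia4 fell in males (4 of 12 members, 7 adjusted over the list alone, list median -0.53). Camera gave the list adjusted p = 0.034 with the preset correlation and adjusted p = 0.578 with an estimated correlation. Calr went from 151 TPM in the other male controls to 66.4 TPM (log2 -1.19, adjusted p = 0.024) and Hspa5 from 124 to 53.1 TPM (log2 -1.21, adjusted p = 0.034). In females without replicate 3, Calr was 129 against 91.0 TPM (log2 -0.51, adjusted p = 0.094). Ttr, the carrier of thyroxine and retinol-binding protein, fell in males from 19.9 ± 6.67 to 2.96 ± 0.558 TPM (log2 -2.36, adjusted p = 9.11e-05) and did not pass in females without replicate 3 (adjusted p = 0.11). Among the added lists in males, the liver list had 1 of 4 higher (Serpina1a, log2 0.97) and 1 lower (Ttr), with 3 and 1 adjusted over the list alone. The airway list had 1 of 1 lower (Sec14l3, log2 -1.75, adjusted p = 0.00565). In the heart (1 gene, Cox6a2), alveolar (1 gene, Napsa) and adipocyte (3 genes) lists limma called 0, with 1, 0 and 0 at an unadjusted p under 0.05, and voom on estimated reads called 1, 1 and 0.

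Levels of male-biased genes in Kl/Kl males can be set beside those of female controls, although the tables were scaled separately and no test was made. Slco1a1 was 12.6 TPM in male controls, 0.0535 TPM in Kl/Kl males (0.0311 without replicate 5) and 0.0159 TPM in female controls (0.00711 without replicate 3). Cyp4a12a was 9.56, 0.174 and 0.104 TPM, and Kap 3813, 184 and 550 TPM, in the same order. The processed pseudogene Gm45315 (chromosome 7, 12531456 to 12531789) fell in both sexes (log2 -3.67 in males and -4.01 in females without replicate 3). It is named after its values were seen, and reads of a parent gene or a strain variant were not tested for it.

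A pair of Kl/Kl males stood above the other libraries in a gene of the adrenal gland, and levels of other adrenal genes are not given here. Cyp21a1, a steroid hydroxylase of the adrenal cortex, was 3.28 TPM in replicate 1 and 24.96 TPM in replicate 2, and at most 0.0738 TPM in the other libraries. Ren1, the renin gene, was 60.1 TPM in Kl/Kl male replicate 1. The haemoglobin gene Hba-a2, which has a near-identical copy, was 628 TPM in Kl/Kl female replicate 2.

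A donor segment around the mutation might change genes near Kl through variants of its strain of origin. Of 136 tested genes within 20 Mb of Kl, 8 passed in males, 6 higher and 2 lower, which is 5.88% (95% exact Clopper-Pearson interval 2.57% to 11.3%). Of the other 8302 genes 491 passed (5.91%, two-sided Fisher exact p = 1). The share was not higher near Kl, and the interval leaves a modest excess open.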
